A study of Caenorhabditis elegans with 6 samples.

How the data were processed

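The samples were early embryo extracts of 3 C. elegans genotypes in 2 replicates each, and per the labels' protocols the replicates were independent cultures. Per the labels, synchronised animals were grown in liquid culture at 20 °C to gravid adults over 60 to 65 h depending on the strain, and embryos were released with hypochlorite. Per the labels' protocols, ribosomal RNA was removed from 5 µg of total RNA with a Ribo-Zero kit, 50 ng went into ScriptSeq v2 libraries, and pools of 3 samples were sequenced for 51 cycles on a HiSeq 2500. Which samples shared a pool, the aligner, the counting tool, the genome build, the handling of reads with several matches and the use of strand in counting are not given in the sources used here.

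The authors deposited raw read counts for 20182 genes, raw read counts for 200566 consecutive windows of 500 bp, and a table of normalized gene values. From the values, the deposited normalized gene values are log2 of the count scaled to the mean library total plus a pseudocount of 8, with a largest deviation of 5.2e-14 when recomputed from the counts. The gene widths in the deposited table are multiples of 3 for 96.63% of genes, as coding lengths are, so untranslated regions appear not to be counted. Gene identifiers were matched to the WBcel235 annotation, which gave a position to 19513 genes; the other 669 have no position and those without a symbol are given by identifier. No positions were converted between builds, and windows are given as deposited. Genes that overlap others, lie opposite another gene or belong to families of near copies are uncertain where reads can be shared.

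Library totals were 30171874 to 45677214 counts over genes and 63512536 to 92014755 over windows, and between 17168 and 17535 genes had at least 1 count. At this depth the 95% Wilson intervals of the shares of window counts extend at most 0.0113 percentage points to either side. Such intervals and the floor of 3 counts per library used for groups at 0 cover counting error only, since the reads carry no molecular identifiers. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 118.8 in wild-type, 69.2 in cec-4 and 49.05 in met-2 set-25. The biological coefficient of variation was 21.7% for genes.

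Differential counts were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr by genotype, TMM scaling and the quasi-likelihood test. All 6 libraries entered a single fit with genotype as the term, so that the 3 genotypes shared an estimate of the spread. After filtering, 13951 genes and 108036 windows were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-adjusted library sizes. Errors after ± are SDs over n = 2. For genes and windows, SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It approximates a standard error and carries no information beyond that test. Fixed gene lists (30 in all, of which the deleted genes were read as single genes and 27 others had 3 or more measured members) were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists. Camera with an estimated correlation and fry were run beside it. The position of calls was tested with two-sided Fisher's exact tests, with arms and centres as outer and middle parts of equal length along each autosome. Because both mutants share the wild-type libraries, 20 simulated sets of unchanged groups, with every library drawn independently from the wild-type means, were compared in the same way.

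The designs, the gene lists, the rule for naming genes and the alternatives, apart from those said to be chosen later, were fixed before the data were examined. The rule takes the targeted genes; up to 10 higher and 10 lower genes of largest log2 fold change among those that passed, had a mean of at least 1 CPM in the higher genotype and separated the replicates of the genotypes compared; up to 4 members of smallest p among the passing members of each list described; and the 5 genes of smallest p where fewer than 5 passed. Up to 5 higher and 5 lower windows follow the same rule with a mean count of at least 10. A gene outside the rule is said to be one.

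The steps were tested on simulated data for met-2 set-25 against wild-type. Over 13951 genes, 26 of 100 changes of 2-fold and 87 of 100 of 4-fold were recovered, with 10 false among 123 calls. Over 108036 windows, 11 of 100 and 82 of 100 were recovered, with 10 false among 103 calls. A list of 40 genes shifted by 0.5 on the log2 scale was recovered and 0 of 50 unshifted lists were called. Alternatives were other scalings (the DESeq2 size factor method, upper quartile, gene-table factors for windows), other filters, DESeq2 1.42.0, limma voom, limma on the authors' log2 values, only the genotypes compared in the fit, stricter thresholds, a replicate block, and each replicate left out in turn. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Mitochondrially encoded genes were listed beforehand but 0 of them are in the gene table, so they were not tested.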

Results

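Early embryos of Caenorhabditis elegans were profiled by RNA sequencing after removal of ribosomal RNA. The 6 libraries came from 3 genotypes with 2 independently grown cultures each: wild-type, a deletion of cec-4, and a deletion of both met-2 and set-25. CEC-4 is a chromodomain protein of the nuclear envelope that binds histone H3 methylated at lysine 9 (H3K9) and holds heterochromatin at the nuclear periphery. MET-2 and SET-25 are the histone methyltransferases that deposit this mark in embryos. The design addresses how transcription responds when chromatin is no longer tethered, or no longer methylated at H3K9. Counts summed over genes came to 45677214 and 41662785 in the wild-type libraries, 44546148 and 36564766 in cec-4, and 30171874 and 37966640 in met-2 set-25. Counts summed over 500 bp windows of the genome lay between 63512536 and 92014755 per library. The last 25 windows of chromosome I, where the ribosomal RNA repeat lies, held 19.3% and 35.3% of the window counts in wild-type, 25.4% and 38.05% in cec-4, and 31.3% and 9.93% in met-2 set-25. The mitochondrial chromosome held between 9.41% and 17.4% of the window counts, with the highest share in met-2 set-25 replicate 2. Vitellogenin transcripts, which mark the adult intestine, were nearly absent. The 6 vitellogenin genes in the table summed to between 12 and 34 counts per library. Of them, 1 was abundant enough to be tested.

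The deleted genes were read first in every library, as a check of the genotype labels. Transcripts of cec-4 (WBGene00017990; WBcel235 IV 7575718 to 7577326, protein coding) stood at 277 ± 7.36 CPM (counts scaled to library size; SD, n = 2) in wild-type, 88.8 ± 15.4 in the cec-4 strain and 300.3 ± 21.5 in met-2 set-25. The cec-4 strain thus held 32.1% of the wild-type level. The H3K9 mono- and dimethyltransferase gene met-2 (WBGene00019883; III 8375300 to 8380848) stood at 379 ± 29.8 CPM in wild-type, 415 ± 2.34 in cec-4 and 76.2 ± 5.88 in met-2 set-25, which is 20.1% of wild-type. The H3K9 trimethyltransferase gene set-25 (WBGene00012802; III 13283824 to 13293090) stood at 104.3 ± 12.8, 116 ± 0.942 and 25.7 ± 3.75 CPM, with 24.6% of the wild-type level left in met-2 set-25. In met-2 set-25 against wild-type, met-2 fell by 2.31 on the log2 scale (SE 0.167, edgeR adjusted p = 0.00204) and set-25 fell by 2.02 (SE 0.193, adjusted p = 0.00466). In the cec-4 strain the log2 fold change of cec-4 was -1.64 (SE 0.181), with an edgeR adjusted p of 0.0955 that did not pass. It passed under 4 of 15 alternatives, all of which are given in the closing section. Which part of each gene was deleted is not given in the sources used here, so counts from outside the deleted part may remain. The annotation places genes on the opposite strand across cec-4 and set-25, whose reads could be mixed with theirs.

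**Figure D1:**
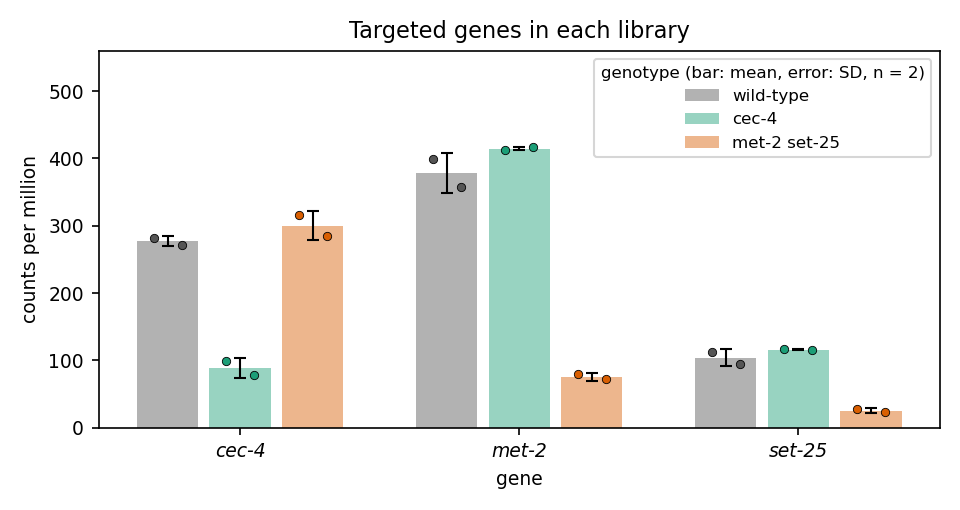
CPM of cec-4, met-2 and set-25 in each of the 6 libraries, grouped by genotype. Points are libraries and the bars give the mean and SD (n = 2). The cec-4 libraries hold 32.1% of the wild-type cec-4 level, and the met-2 set-25 libraries hold 20.1% and 24.6% of the met-2 and set-25 levels.

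The comparison of cec-4 with wild-type embryos asks what changes when the anchor alone is missing. The chemoreceptor gene srw-85, of the serpentine receptor class w family (WBGene00005832; WBcel235 V 19429387 to 19431136, protein coding), rose from 0.102 ± 0.00988 CPM in wild-type to 4.93 ± 1.96 CPM in cec-4 (SD, n = 2). Its log2 fold change was 5.54 (SE 0.471, edgeR adjusted p = 0.025), from 5 and 4 counts in the wild-type libraries to 156 and 216 in the cec-4 libraries. No other gene of the 13951 tested was higher. With edgeR 0 genes were lower, with 131 genes in either direction at an unadjusted p under 0.05. That is a smaller share of the 13951 than the 0.05 that unchanged genes would give on average. The test was thus conservative here, and the lack of further calls does not show that other genes were unchanged. With DESeq2 1 gene was lower, cec-4 itself, and 0 with limma voom. The genes of next smallest p, given as values that did not pass, were the pseudogene W06A11.4 (log2 fold change 1.34, SE 0.279), WBGene00010213 (-1.38, SE 0.311) and the neuropeptide receptor gene npr-15 (-3.99, SE 0.911, with 0 and 1 counts in the cec-4 libraries), each with an edgeR adjusted p of 1. The srw-85 call ended with upper quartile scaling, with limma voom, with only these 2 genotypes in the fit, and without wild-type replicate 1, met-2 set-25 replicate 1 or met-2 set-25 replicate 2. There the adjusted p went up to 0.18, and over the alternatives the log2 fold changes lay between 3.96 and 5.90. Reads of srw-85 could be shared with other members of this large family, since the treatment of ambiguous reads is not given in the sources used here.

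Gene groups differed little in size between cec-4 and wild-type, and apart from srw-85 among 190 measured chemoreceptor genes no member of a fixed list passed over all genes tested. Maternal early embryo genes had a median log2 fold change of 0.18 with 30 of 36 members positive (limma camera adjusted p = 3.07e-06; adjusted p = 0.886 with an estimated correlation between genes), and cell cycle and DNA replication genes one of 0.13 with 34 of 43 positive (adjusted p = 2.47e-05; 0.886 with an estimated correlation). Nuclear envelope and lamina genes had a median of 0.14 with 18 of 19 positive (adjusted p = 1.45e-05; 0.886 with an estimated correlation), and dosage compensation and sex determination genes one of 0.15 with 17 of 21 positive (adjusted p = 0.000599; 0.886 with an estimated correlation). Collagen genes lay lower, with a median of -0.34 and 15 of 78 positive (adjusted p = 1.02e-05; 0.886 with an estimated correlation), as did histone genes, with a median of -0.16 and 6 of 25 positive (adjusted p = 0.000497; 0.773 with an estimated correlation). The other lists called by camera, each with an adjusted p = 0.886 with an estimated correlation, were germline granule genes (median 0.07, adjusted p = 0.00311) and nuclear RNAi factors (0.06, 0.035) on the higher side. On the lower side were neuropeptide genes (-0.21, 0.02), ribosomal protein genes (-0.06, 0.02), intracellular pathogen and immune response genes (-0.16, 0.035) and nuclear hormone receptor genes (-0.08, 0.0413). In each of these 12 lists 0 members passed adjusted over the list alone. With a replicate block 2 of the 12 lost their call. The fits with a library left out, given next, held no such block, so genotype and replicate number are partly mixed there. Without wild-type replicate 2, 11 of the 12 lists lost their call or turned direction, among them maternal genes (adjusted p = 0.705), collagen genes (0.929), cell cycle genes (0.929) and nuclear envelope genes (0.266). Without cec-4 replicate 1, 7 were lost, and without cec-4 replicate 2, 3. Nuclear hormone receptor genes (0.0538) were lost without met-2 set-25 replicate 1, and histone genes (0.219) without wild-type replicate 1.

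Among 108036 windows of 500 bp tested, 2 were higher in cec-4 than in wild-type, and they adjoined each other at V 19429501 to 19430500. The windows held 127 and 185, and 91 and 141, counts in the cec-4 libraries against 1 and 1, and 7 and 5, in wild-type, with log2 fold changes of 7.18 (SE 0.55, edgeR adjusted p = 0.000432) and 4.33 (SE 0.442, adjusted p = 0.00779). With edgeR 0 windows were lower, with 1918 in either direction at an unadjusted p under 0.05. That is again a smaller share than the 0.05 that unchanged windows would give on average. The absence of lower windows thus does not show that none fell. With a replicate block 1 window was lower. No other tool was run on windows. The genome build of the window table is not named in the sources used here and its chromosome ends differ from those of WBcel235, so windows were not assigned to genes. Taken as WBcel235 positions, both windows would lie within srw-85 (V 19429387 to 19431136), so they may be no result apart from the rise of that gene. With scaling factors from the gene table the window at V 19429501 was no longer called and the other still was. Without wild-type replicate 1, 16 windows were called, and 5 without cec-4 replicate 1 or without wild-type replicate 2.

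The comparison of met-2 set-25 with wild-type embryos asks what changes when H3K9 methylation is lost. Among 13951 genes, 92 rose and 4 fell. With DESeq2 175 rose and 10 fell, with no low-count filter 193 and 10, and at an adjusted p under 0.01 14 and 2. A replicate block gave 183 and 8. The chemoreceptor genes srw-85 and sri-62 rose most among genes at 1 CPM or more in met-2 set-25. Transcripts of srw-85 went from 0.102 ± 0.00988 to 7.91 ± 0.101 CPM, a log2 fold change of 6.22 (SE 0.475, n = 2, edgeR adjusted p = 0.00204). Those of sri-62, of serpentine receptor class i (WBGene00005574; WBcel235 II 2696939 to 2698478), went from 0.0348 ± 0.0183 to 1.85 ± 0.131 CPM (5.63, SE 0.58, adjusted p = 0.0134). Of the 10 higher genes named by size, the best expressed were F40D4.13 (WBGene00009572; V 17155874 to 17157254), at 20.8 ± 1.46 against 1.19 ± 0.0243 CPM (log2 fold change 4.13, SE 0.338, adjusted p = 0.00265), and mihp-1 (WBGene00007219; I 13402448 to 13404106), at 16.9 ± 0.226 against 0.929 ± 0.138 CPM (4.18, SE 0.306, adjusted p = 0.00204). Y102A5C.36 (WBGene00044213; V 16926922 to 16927445) rose from 0.464 ± 0.149 to 8.71 ± 0.37 CPM (4.22, SE 0.371, adjusted p = 0.00359).

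The other higher genes named by size were WBGene00013630, which has no position in the annotation (log2 fold change 4.93, SE 0.627), Y54F10BM.3 (4.75, SE 0.732), Y49E10.25 (4.42, SE 0.54), the C-type lectin gene clec-92 (4.33, SE 0.576) and K02H11.9 (4.18, SE 0.625), with edgeR adjusted p between 0.0156 and 0.0307. Over all 92 genes the median log2 fold change was 2.51, also with the 1 gene at 0 counts in wild-type set to its bound of at least 6.68-fold. In wild-type, 44 of the 92 lay under 1 CPM. Besides met-2 and set-25 themselves, the genes that fell were T08B2.11 (WBGene00020349; I 6221245 to 6223115), from 9.37 ± 0.0889 to 2.15 ± 0.228 CPM (log2 fold change -2.12, SE 0.272, adjusted p = 0.0198), and R11A8.1 (WBGene00011236; IV 10355046 to 10357172), from 5.44 ± 1.75 to 1.32 ± 0.196 CPM (-2.05, SE 0.344, adjusted p = 0.0446). The R11A8.1 call ended with upper quartile scaling, limma voom, a minimum of 1 CPM, only these 2 genotypes in the fit, or without wild-type replicate 1 or either met-2 set-25 library. Genes on the opposite strand overlap sri-62, Y49E10.25 and R11A8.1, so their counts are uncertain. With a single met-2 set-25 library the count of calls fell to 10 without replicate 1 and to 11 without replicate 2, of which 9 and 10 were among the 92 higher genes. The genes srw-85, mihp-1, F40D4.13, Y102A5C.36 and met-2 were called with each of the 6 libraries left out. Without wild-type replicate 1, 51 of the 92 were called, and without wild-type replicate 2, 55.

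**Figure D2:**
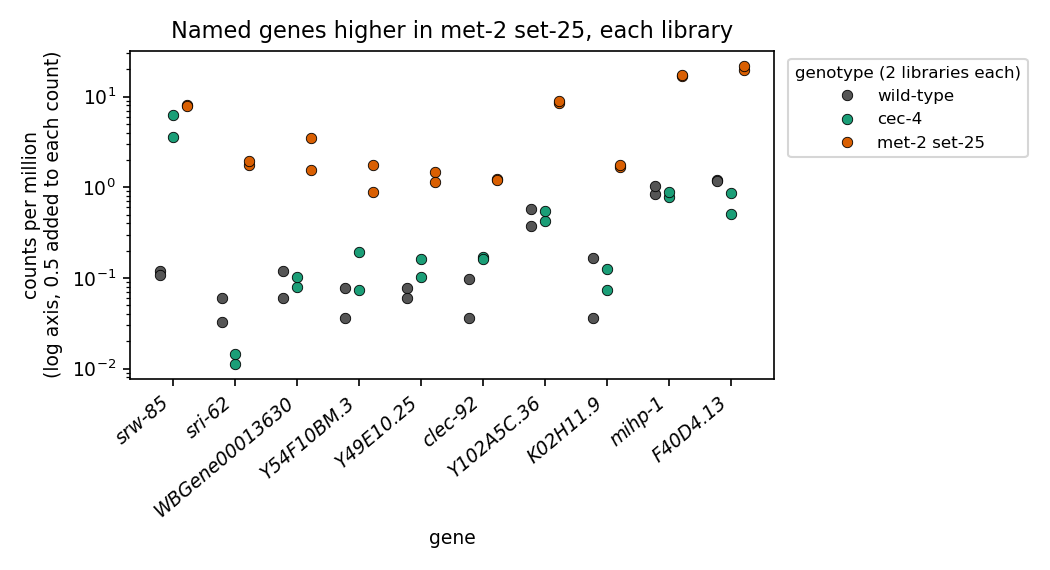
CPM, on a log axis, of the 10 named genes higher in met-2 set-25 than in wild-type, one point per library with colours for the 3 genotypes. For srw-85 the cec-4 libraries also lie above wild-type, at 4.93 ± 1.96 CPM, and for F40D4.13 and mihp-1 they lie near wild-type.

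By gene family, F-box and MATH or BTB domain genes, a large set of predicted substrate adaptors of ubiquitin ligases, lay higher in met-2 set-25 than in wild-type, with a median log2 fold change of 0.23 and 228 of 303 measured members positive (camera adjusted p = 4.88e-08; adjusted p = 0.854 with an estimated correlation). In this family 4 members rose over all genes tested and 14 adjusted over the list alone. The 4 were bath-19 (2.57), fbxa-136 (2.46), bath-3 (1.77) and fbxa-114 (1.52), with edgeR adjusted p between 0.0219 and 0.0484. Spermatogenesis genes had a median of 0.49 with 18 of 26 positive (adjusted p = 2.8e-05; adjusted p = 0.324 with an estimated correlation). Of these, 2 rose over all genes and 6 adjusted over the list alone, with the sperm casein kinase gene spe-6 at 12.64 ± 1.61 against 3.37 ± 0.311 CPM (1.91, SE 0.281, adjusted p = 0.0267) and nspd-7 at 0.956 ± 0.1 against 0.103 ± 0.0225 CPM (3.17, SE 0.489, adjusted p = 0.0307). Chemoreceptor genes had a median of 0.12 with 113 of 190 positive (adjusted p = 0.00463; adjusted p = 0.31 with an estimated correlation). In that family srw-85, sri-62 and sre-50 (2.93, SE 0.493, adjusted p = 0.0446) rose over all genes, and adjusted over the list alone 10 rose and 1 fell. C-type lectin genes had a median of 0.17 with 51 of 87 positive (adjusted p = 0.00682; adjusted p = 0.854 with an estimated correlation), where clec-92, clec-126 (3.57) and clec-73 (3.83) rose over all genes and 5 members adjusted over the list alone. The F-box, chemoreceptor and C-type lectin genes named here all lie in the chromosome arms, defined below. Position was not held equal in any of the list tests, so these calls may restate the excess of higher genes there. Among 86 homeobox genes ceh-91 rose, from 47.3 ± 3.02 to 118 ± 5.95 CPM (1.31, SE 0.17, adjusted p = 0.0205), while the list as a whole was not called (median -0.14, camera adjusted p = 0.0789).

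Stage and tissue markers shifted by small amounts. Maternal early embryo genes had a median log2 fold change of -0.25 with 7 of 36 positive (camera adjusted p = 0.00136), and early zygotic genes one of 0.18 with 32 of 45 positive (adjusted p = 0.0432). With an estimated correlation neither these nor the other lists called in this paragraph were called, each with an adjusted p = 0.854. Muscle genes had a median of -0.34 with 3 of 33 positive (adjusted p = 0.00397), epidermis and cuticle genes one of -0.22 with 8 of 39 positive (adjusted p = 0.00958), and heat shock and protein folding genes one of -0.14 with 1 of 15 positive (adjusted p = 0.00397). Collagen genes had a median of 0.11 with 43 of 78 positive (adjusted p = 0.0207), with 1 member higher adjusted over the list alone. The H3K9 methylation and heterochromatin factors had a median of -0.04 with 8 of 20 positive (adjusted p = 0.0207), and the deleted genes met-2 and set-25 were the 2 members that fell. Without the deleted genes (cec-4 also taken out, 17 members left), an alternative chosen after the data were seen, the list was not called (camera adjusted p = 0.436). Apart from met-2 and set-25 none of the members of these 7 lists passed over all genes. Markers of pharynx (median 0.26, adjusted p = 0.0707), neurons (-0.19, 0.0707), germline (0.04, 0.247) and intestine (-0.13, 0.436) were not called. Of the 11 lists called, spermatogenesis alone was called with each of the 6 libraries left out. Calls ended or turned without wild-type replicate 1 for maternal (adjusted p = 0.913), C-type lectin (0.583), collagen (0.385), H3K9 (0.373) and heat shock genes (0.0736), and without wild-type replicate 2 for muscle (0.256), F-box (0.173), epidermis (0.115), chemoreceptor (0.0766) and early zygotic genes (0.0511). They did so without met-2 set-25 replicate 1 for early zygotic (0.907), epidermis (0.247) and muscle genes (0.106), and without met-2 set-25 replicate 2 for maternal (0.691), collagen (0.653), H3K9 (0.46), heat shock (0.326) and C-type lectin genes (0.146).

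Over 500 bp windows, 482 were higher and 26 lower in met-2 set-25 than in wild-type, in 260 and 9 runs of adjoining windows. The longest run of higher windows had 11 windows, at IV 2903501 to 2909000. The window at V 19430001 to 19430500 rose from 0.0114 ± 3e-04 to 2.96 ± 0.349 CPM (log2 fold change 7.84, SE 0.542, n = 2, edgeR adjusted p = 2.28e-05). At V 19430501 to 19431000 both wild-type libraries had 0 counts and met-2 set-25 had 0.46 ± 0.117 CPM, at least 13.5-fold higher with a floor of 3 counts per library. The windows that fell most lay on chromosome III, where III 13288501 to 13289000 went from 7.86 ± 0.675 CPM to 0 counts in both met-2 set-25 libraries, at least 172-fold lower. The window III 8376501 to 8377000 went from 24.3 ± 2.9 to 0.0733 ± 0.0662 CPM (-8.45, SE 0.426, adjusted p = 1.1e-06). Taken as WBcel235 positions, these windows would lie within the deleted genes set-25 (III 13283824 to 13293090) and met-2 (III 8375300 to 8380848). Their fall may thus be the deletions themselves and is not read as a response to them. With scaling factors taken from the gene table, 290 windows were higher and 23 lower, and the median log2 fold change of all windows was -0.12 in place of -0.03. Without met-2 set-25 replicate 1, 242 windows were called, without met-2 set-25 replicate 2, 169, and without wild-type replicate 1, 820.

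Genes that rose in met-2 set-25 lay mostly in the chromosome arms, taken as the outer parts when each of the 5 autosomes was divided into 3 equal lengths. Of 6795 genes tested in the arms 72 rose (1.06%), and of 4744 in the centres 8 rose (0.169%), an odds ratio of 6.34 (95% interval 3.05 to 15.3; two-sided Fisher's exact test p = 1.39e-09, Benjamini-Hochberg adjusted p = 4.63e-09 over 10 tests). On the X chromosome 4 of 2006 genes rose, against 80 of 11539 on the autosomes (odds ratio 0.286, interval 0.0761 to 0.763, adjusted p = 0.0134). The share on X (0.199%) was near that of the autosome centres (0.169%), so this difference may restate the excess in the arms. Windows gave the same direction, with 420 of 56485 higher in the arms and 36 of 33407 in the centres (odds ratio 6.94, interval 4.93 to 10.1, adjusted p = 2.46e-46). Chromosomes II and V held 21 and 22 of the higher genes, I, III and IV held 13, 15 and 9, and 8 had no position in the annotation. Genes and windows are not independent replicates, and neighbouring windows of a transcript are counted separately.

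**Figure D3:**
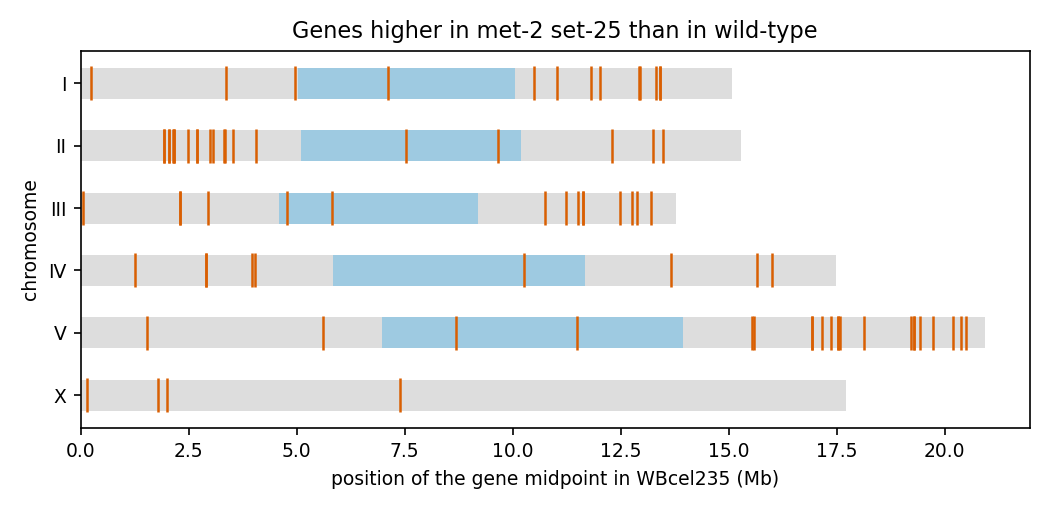
Positions of the genes higher in met-2 set-25 than in wild-type along the 5 autosomes and X (WBcel235, in megabases). Each tick is the midpoint of a gene, and blue marks the middle part of each autosome. Most ticks lie outside the blue parts, with 72 genes in the arms, 8 in the centres and 4 on X.

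The met-2 set-25 strain was also compared with cec-4 directly, the test of the difference between the mutants. Here 85 genes were higher in met-2 set-25 and 4 lower. With DESeq2 220 were higher and 20 lower, with no low-count filter 238 and 18, with only these 2 genotypes in the fit 177 and 11, and with limma on the authors' values 164 and 6. A replicate block gave 280 and 15. At an adjusted p under 0.01 they numbered 18 and 2. The chemoreceptor gene sri-62 had 0 counts in both cec-4 libraries and 1.85 ± 0.131 CPM in met-2 set-25 (n = 2), at least 23.7-fold higher with a floor of 3 counts per library (edgeR adjusted p = 0.00808). ZC190.10 (WBGene00022544; V 8692198 to 8696318) was at 2.24 ± 0.0702 against 0.0519 ± 0.00923 CPM (log2 fold change 5.36, SE 0.517, adjusted p = 0.00514), F40D4.13 at 20.8 ± 1.46 against 0.68 ± 0.259 (4.91, SE 0.357, adjusted p = 0.00179) and mihp-1 at 16.9 ± 0.226 against 0.824 ± 0.0742 (4.36, SE 0.311, adjusted p = 0.00179). The others named by size were WBGene00013630 (4.97), C33C12.4 (4.31), Y102A5C.36 (4.22), K02H11.9 (4.22), the pseudogene Y73B3A.13 (3.77) and Y37H2A.10 (3.72), with adjusted p between 0.00216 and 0.0354. The genes that fell were met-2 (-2.45, SE 0.168, adjusted p = 0.00179), set-25 (-2.18, SE 0.193, adjusted p = 0.00439), R11A8.1 (-2.16, SE 0.345, adjusted p = 0.0381) and T08B2.11 (-2.03, SE 0.272, adjusted p = 0.0214), and cec-4 itself was higher in met-2 set-25 (1.76, SE 0.182, adjusted p = 0.00724). Without met-2 set-25 replicate 1 or 2 the calls numbered 9, without cec-4 replicate 1, 23, and without cec-4 replicate 2, 13. Without wild-type replicate 1 or 2, which also changes the filter and the scaling, they numbered 166 and 211. With each of the 6 libraries left out, F40D4.13, mihp-1, Y102A5C.36, Y73B3A.13 and met-2 were called.

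In gene groups, maternal early embryo genes lay lower in met-2 set-25 than in cec-4, with a median log2 fold change of -0.44 and 5 of 36 positive (camera adjusted p = 3.71e-08). With an estimated correlation neither this list nor any of the other 12 called here was called, with an adjusted p = 0.616 for spermatogenesis and histone genes, 0.895 for muscle and 0.805 for the others. F-box and MATH or BTB domain genes lay higher, with a median of 0.30 and 229 of 303 positive (adjusted p = 9.63e-07). Of these, 4 rose over all genes, and adjusted over the list alone 22 rose and 2 fell, with fbxa-136 at 3.32 and bath-19 at 2.63. Collagen genes had a median of 0.39 with 62 of 78 positive (adjusted p = 3.52e-05). The collagen genes col-74, at 62.9 ± 17.1 against 11.1 ± 3.95 CPM (2.50, SE 0.359, edgeR adjusted p = 0.0267), and col-45 (3.56, SE 0.563, adjusted p = 0.0364) rose over all genes and 12 members adjusted over the list alone. Histone genes (median 0.24, 21 of 25 positive, camera adjusted p = 0.00166), neuropeptide genes (0.46, 45 of 61, adjusted p = 0.00277), C-type lectin genes (0.31, 58 of 87, adjusted p = 0.00166), spermatogenesis genes (0.50, 18 of 26, adjusted p = 0.00439) and immune response genes (0.29, 40 of 58, adjusted p = 0.0118) lay higher. Nuclear envelope genes (-0.17, 3 of 19, adjusted p = 0.00202), dosage compensation genes (-0.21, 4 of 21, adjusted p = 0.00737), muscle genes (-0.19, 6 of 33, adjusted p = 0.0312), homeobox genes (-0.13, 30 of 86, adjusted p = 0.0332) and the H3K9 factors (-0.06, 5 of 20, adjusted p = 0.0207) lay lower. Of the H3K9 factors met-2 and set-25 fell and cec-4 rose over all genes, and without these deleted genes the list was not called (adjusted p = 0.0981). The synaptonemal complex gene syp-1 rose from 55.3 ± 6.69 to 137 ± 20.9 CPM (1.31, SE 0.207, edgeR adjusted p = 0.0364), in a germline list that was not called (camera adjusted p = 0.492). A score of early zygotic minus maternal genes (log2) was -2.593 and -3.038 in cec-4 and -2.209 and -2.078 in met-2 set-25. It holds the maternal genes themselves, so it is no separate measure of them. A difference in embryo age between the cultures stays open as a source of these list differences. Calls for maternal, F-box, collagen and histone genes held with each of the 6 libraries left out. The other 9 ended or turned: without cec-4 replicate 1, H3K9 (adjusted p = 0.154), immune (0.101), C-type lectin (0.0621) and neuropeptide genes (0.0578); without cec-4 replicate 2, muscle (0.52) and homeobox genes (0.121); without met-2 set-25 replicate 1, muscle (0.273) and spermatogenesis genes (0.0566); and without met-2 set-25 replicate 2, H3K9 (0.217), homeobox (0.174), dosage compensation (0.164), nuclear envelope (0.102) and immune genes (0.0762).

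Genes higher in met-2 set-25 than in cec-4 also lay mostly in the arms, with 67 there and 8 in the centres (odds ratio 5.89, interval 2.82 to 14.2, Fisher's exact test adjusted p = 2.32e-08). Windows numbered 535 higher and 32 lower, with 448 of the higher ones in the arms and 48 in the centres (odds ratio 5.56, interval 4.12 to 7.65, adjusted p = 1.29e-43). The window at II 2697001 to 2697500 had 0 counts in cec-4 and 0.796 ± 0.13 CPM in met-2 set-25 (n = 2), at least 22.3-fold higher. The window X 124001 to 124500 rose from 0.0167 ± 0.0236 to 0.805 ± 0.192 CPM (log2 fold change 5.40, SE 0.717, edgeR adjusted p = 0.00259). With gene-table scaling factors 296 windows were higher and 25 lower, and the median of all windows was -0.20 in place of -0.00158. Without cec-4 replicate 2 the called windows numbered 227, without met-2 set-25 replicate 1 or 2, 377 and 220, and without wild-type replicate 1 or 2, 1586 and 1568.

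The effects of both mutants were then set side by side. The gene srw-85 was the 1 gene called higher in both mutants against wild-type. By chance 0.00659 would be shared by independent lists of 1 and 92 genes among 13951. In 20 simulations of unchanged groups against shared wild-type libraries 0 genes were shared, but with a mean of 0.1 higher calls in each group hardly any could be. Matched by rank, a comparison chosen after the data were seen, the gene of smallest p in one simulated group was among the first 92 of the other in 11 of 20 simulations. Ranks leave the size of the srw-85 change aside. In cec-4 the 92 genes higher in met-2 set-25 had a median log2 fold change of 0.05 (quartiles -0.10 to 0.26), with 52 of 92 positive. The 85 genes higher in met-2 set-25 than in cec-4, a set whose choice favours low values in cec-4, had a median of -0.05 there with 34 of 85 positive. Between these sets 74 genes were shared, so that they were higher in met-2 set-25 than in both other genotypes, and met-2, set-25, T08B2.11 and R11A8.1 were lower than in both. These lists share the met-2 set-25 libraries, so part of their overlap may come from them. Across all genes the log2 fold changes of both mutants correlated with r = 0.117, against 0.483 (0.472 to 0.501) in the simulations. The covariance was 0.0227 against 0.0814 simulated, and 48.9% of genes had the same sign against 66.4% simulated. The simulations drew each library independently, so deviations that libraries of different genotypes have in common are left out of the simulated values, and the gap to them is not read as an effect. Genes are not independent replicates, and the 2 wild-type libraries were too few to be split between the comparisons, so part of any overlap may come from the shared controls.

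**Figure D4:**
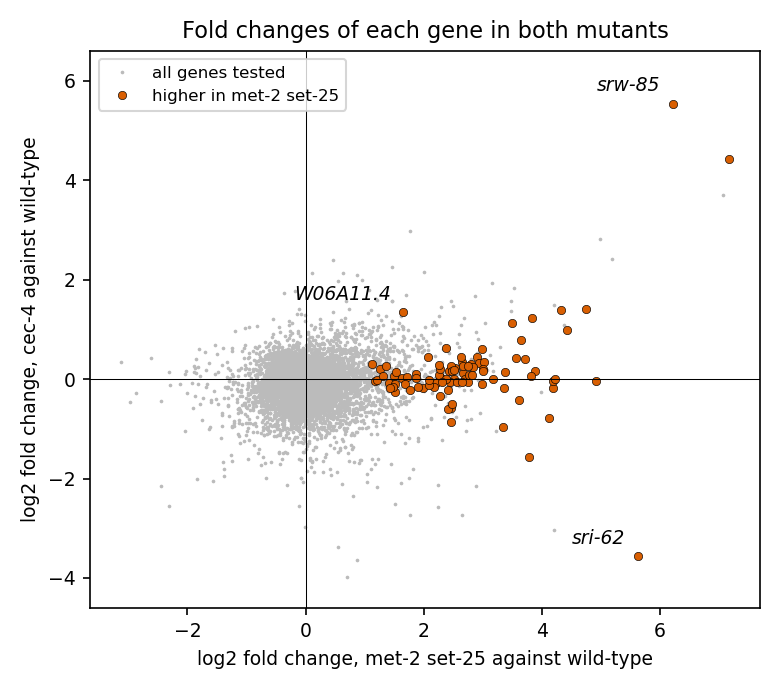
Log2 fold change against wild-type of each of 13951 genes in met-2 set-25 (horizontal) and cec-4 (vertical), with the 92 genes higher in met-2 set-25 in orange. Most orange points lie near 0 on the vertical axis and srw-85 lies at 6.22 and 5.54. Transcripts of sri-62 have 0 counts in cec-4 and the point at 7.18 has 0 counts in wild-type, so their fitted values depend on the prior count and are no bounds.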

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

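The fry test in either direction and the lists without the deleted genes were chosen after the data had been seen; the other alternatives were planned. Genes called in cec-4 against wild-type (1) numbered 0 with upper quartile scaling, limma voom, only the 2 genotypes in the fit or an adjusted p under 0.01, and 2 with no low-count filter, the authors' values in limma or DESeq2, where the added gene was cec-4 itself (adjusted p = 0.000478, 0.0371 and 9.78e-08). In met-2 set-25 against wild-type the 96 became 203 with no filter, 185 with DESeq2 and 16 at an adjusted p under 0.01, and against cec-4 the 89 became 256, 240 and 20, besides 188 with only the 2 genotypes and 170 with the authors' values. Called windows numbered 1, 313 and 321 in the 3 comparisons with gene-table scaling, which moved the median of all windows to 0.09, -0.12 and -0.20. In the labels replicates of different genotypes share only a number, though same-numbered deviations correlated with 0.531 (wild-type and cec-4), 0.295 (wild-type and met-2 set-25) and 0.19 (cec-4 and met-2 set-25), and the second principal component (31.5% of the variance) separated the numbers. With the replicate block the gene calls numbered 2 (srw-85 and cec-4, the latter at -1.65 with an adjusted p of 0.0323), 191 and 295 and the called windows 3, 852 and 1117, and 0 of the named genes and windows lost their call; 2 of the 12 lists in cec-4, 2 of the 11 in met-2 set-25 against wild-type and 0 of the 13 against cec-4 did. Camera with an estimated correlation called 0 lists in each comparison, fry with a direction 1 in each, and fry in either direction 1, 4 and 4. With directional fry 12 of the 12, 10 of the 11 and 13 of the 13 lists called by camera lost their call. In cec-4 against wild-type and in met-2 set-25 against cec-4 the list it called was thus none of those. Without the deleted genes 12, 10 and 12 lists were called, and the H3K9 factors were not (adjusted p = 0.436 and 0.0981 where they had been). With a replicate left out, where the lone library is assumed to vary like the other groups, gene calls ranged from 0 to 1, 10 to 107 and 9 to 211, called windows from 2 to 16, 169 to 820 and 220 to 1586, and lists in cec-4 from 9 to 20. Lists that turned direction without a replicate had these lowest and highest adjusted p over all the replicates left out, not only the one named. Germline granule genes, higher in cec-4 in the main fit, were called lower without wild-type replicate 2. Without wild-type replicate 2, in cec-4: nuclear RNAi 4.52e-05 and 0.36, germline granule 1.23e-10 and 0.182, maternal 9.26e-12 and 0.705, collagen 1.55e-09 and 0.929, nuclear hormone receptor 4.52e-05 and 0.219, ribosomal protein 0.00146 and 0.571, intracellular pathogen 4.52e-05 and 0.338, and cell cycle genes 5.35e-08 and 0.929. In met-2 set-25 against wild-type: early zygotic 1.34e-06 and 0.907, muscle 1.1e-08 and 0.256 and epidermis 3.91e-08 and 0.247 without wild-type replicate 2, and maternal 1.28e-12 and 0.913 and collagen 1.74e-06 and 0.653 without wild-type replicate 1. Against cec-4: muscle 4.78e-07 and 0.52 without cec-4 replicate 2. Of 24 called named genes in met-2 set-25 against wild-type, 4 lost their call under some other alternative and 19 without some replicate; against cec-4, of 26, 0 and 21 did, and 0 reversed. Arm odds ratios of higher genes and windows stayed between 3.94 and 6.32 with arms drawn as the outer 25% at each end or with the block, and in cec-4, with 1 gene and 2 windows higher, the exact p lay between 0.206 and 1. The X odds ratio of genes higher in met-2 set-25 than in wild-type went from 0.286 to 0.439 with the block. Apart from fewer libraries or genes tested, the cause was not tested.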

Other observations

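Of the tests below, both of those on srw-85 and the one on a held-out library were chosen after the result was seen, as were the genes of the next paragraph and the test of pseudogenes; the others were fixed before their results were seen. The held-out test took the place of earlier versions that could not decide, since their genes had been chosen with met-2 set-25 or wild-type libraries in which they were then measured.

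The enu-3 family, outside the fixed lists, had 5 members in the gene table, and 4 of them rose in met-2 set-25 against wild-type. The log2 fold changes were 2.91 (SE 0.275) for enu-3.2, 2.63 (SE 0.297) for enu-3.3, 2.66 (SE 0.317) for enu-3.5 and 2.47 (SE 0.304) for enu-3.6 (edgeR adjusted p = 0.00466, 0.0123, 0.0156 and 0.0156). The fifth, enu-3.1, stood at 1.29 (SE 0.445, adjusted p = 0.553). In WBcel235 enu-3.3 lies at I 4959217 to 4961526 and enu-3.2, enu-3.1, enu-3.6 and enu-3.5 lie on chromosome III from 4783194 to 12880701, so the family is spread over distant loci, though reads may be shared among such paralogs, a source left untested. In cec-4 the 5 log2 fold changes lay between 0.16 and 0.69, each with an adjusted p of 1.

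Other genes with known functions were among the 92. They included prde-1, needed for making piRNA precursors (9.59 to 29.7 CPM, log2 fold change 1.63, SE 0.263), the co-Smad gene sma-4 of TGF-beta signalling (10.4 to 48.4 CPM, 2.21, SE 0.223), the ABC transporter gene abt-5 (7.9 to 49.8 CPM, 2.65, SE 0.249) and the phosphodiesterase gene pde-1 (1.7 to 9.67 CPM, 2.51, SE 0.353), with edgeR adjusted p of 0.0378, 0.00605, 0.00466 and 0.023. Annotated pseudogenes were among the higher genes more often than coding genes, with 11 of 275 (4%) against 72 of 13264 (0.543%), an odds ratio of 7.63 (interval 3.6 to 14.7, Fisher's exact test p = 8.79e-07, adjusted p = 1.76e-06 over 2 tests). Against cec-4 it was 6.56 (Fisher's exact test p = 2.49e-05). Neither position nor expression was held equal in these tests, so they may restate the excess in the chromosome arms.

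The gene srw-85 was higher in the cec-4 libraries than in wild-type, and its difference between the mutants did not pass. RNA from met-2 set-25 in the cec-4 libraries would bring the other higher genes along, yet those 91 lay at a median of 0.839% of the way from wild-type to met-2 set-25 (quartiles -1.67% to 3.89%), against 61.8% for srw-85, and W06A11.4, at 71.3%, was the 1 above 50% of the srw-85 value. Scaling or depth is argued against by counts scaled to the library total (CPM without TMM), where the lower cec-4 library (3.5) was 32 times the higher wild-type one (0.109). A sequence variant at this locus carried by both mutant strains, strain background, reads shared with related receptors, and the mutations themselves stay open as explanations. A response to loss of the anchor and of the mark alike is a hypothesis that may be followed up at srw-85.

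Genes higher in met-2 set-25 lay in chromosome arms, and near each other. Over 10 strata of mean expression the common odds ratio was 5.57 (interval 2.68 to 13.4). That mean was taken over all 6 libraries, met-2 set-25 included, so genes that rose could move into higher strata. Lower wild-type expression in the arms is therefore not settled by it and stays open. Double counting of neighbours as the whole cause is argued against by an odds ratio of 5.46 (2.6 to 13.2) with called genes within 10 kb counted once. Of 84 positioned genes 20 lay within 10 kb of another, against a mean of 3.96 and a highest of 17 in 10000 draws from the same chromosomes and arm or centre parts (permutation p = 1e-04, the smallest the draws can give). The pairs were mihp-1 and W05H12.2, F52C6.4 and F52C6.14, bath-3 and bath-19, set-11 and sri-62, Y54F10BM.3 and Y54F10BM.9, Y66A7A.4 and ceh-91, Y54G2A.36 and Y54G2A.21, Y102A5C.2 and Y102A5C.36, fbxa-136 and C18D4.6, and F55C9.3 and F55C9.5. Loss of a repressive mark over shared stretches of the arms is a hypothesis that may account for this; reads shared between related neighbours and transcripts running into the next gene stay open, and no map of H3K9 methylation was used here.

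The rise of 92 genes in met-2 set-25 was weighed against embryo age and against the library with the low ribosomal share. An early zygotic minus maternal score differed by 0.441 (log2) between met-2 set-25 and wild-type, where the higher genes differed by 2.71; between cec-4 replicate 2 and wild-type replicate 1, which differed by 0.549 in the score, the higher genes differed by 0.105, or 3.11% of the change per unit of score (16.6% between the wild-type replicates and 7.07% between those of cec-4). The 92 higher genes of smallest p chosen without met-2 set-25 replicate 1 and wild-type replicate 2 differed by a median of 2.69 between the libraries used and 1.96 between those held out, or 72.69% of it, with 63 of 92 positive and a median of -0.0079 over all genes. With wild-type replicate 1 held out in place of 2, the values were 2.55 and 2.28 (89.72%, 92 of 92 positive, and -0.000276 over all genes). The depth or ribosomal share of replicate 2 is thus argued against as the whole cause. Both met-2 set-25 libraries scored higher (-2.209 and -2.078) than all wild-type and cec-4 libraries (-3.038 to -2.489). The age values thus show little change of the higher genes within the lower range of scores only. The higher genes were also chosen in a fit that held these libraries, so the values cannot settle age as a cause. Age, the genotype, as a hypothesis, and other differences between the strains stay open, and each may contribute.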
